A study of Homo sapiens with 9 samples.

How the data were processed

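The libraries came from SH-SY5Y, an established human neuroblastoma cell line, carrying a stably integrated short hairpin RNA. One hairpin was a negative control (shNC) and the other was directed against TDP-43 (shTDP43), the RNA- and DNA-binding protein encoded by TARDBP. Per the labels' protocols, transduced cells were selected with puromycin at 2 µg/mL for 2 weeks and kept at 1 µg/mL. DNA:RNA hybrids were measured by DRIP-seq: nucleic acids were cut with 5 restriction enzymes, and 6 µg was immunoprecipitated with the hybrid-specific antibody S9.6 and sequenced. For each genotype 3 libraries were made without RNase H and 1 after 6 h of RNase H, an enzyme that removes the RNA strand of such hybrids. The labels also name 1 input library, which was not analysed here. The labels do not say whether the replicates of a genotype came from separately transduced lines. The p-values therefore measure only the spread between these libraries.

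Peak lists were made per library and not from pooled replicates, per the labels and the peak names in the files. The submitters' processing notes name Bowtie2 2.4.4, SAMtools, MACS2 2.2.6 and the hg38 build, without settings. The control used for peak calling is not given in the sources used here. Each peak carries a ratio, the fold enrichment over local background, as the authors' peak caller gave it. It also carries −log10 p and −log10 q values from the authors' deposited lists, whose lowest −log10 q lay just above 1.30 in each library. The score column of the deposited lists is the whole part of 10 times the −log10 q. These values belong to single peaks and were used only to describe or filter peaks within a list, never to compare a peak between libraries. The lists hold no read counts, so no count model was used.

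Depth was read back from the lists. MACS2 writes a fold and a p-value from the same pileup and background, so both can be solved for at a peak summit. Of 5000 summits tried per library, between 99.5% and 99.9% gave a whole-number pileup within 0.001 of the printed −log10 p. The lowest background pileup among these summits is given below as a relative depth.

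Gene positions came from the GRCh38.p14 RefSeq annotation, which shares its chromosome coordinates with hg38. It was used without strand, exon or sequence information, so a peak was placed in a gene span, at a gene end or outside coding genes, and not in an exon, intron or repeat. The planned promoter share was therefore computed as the share of covered length within 1 kb of either end of a protein-coding gene. Analyses used chromosomes 1 to 22 and X. The value per gene and library was the length of the gene span plus 1 kb on each side that lay under peaks. It was scaled to the median library total of covered length, and 100 bp was added before taking log2. The 12810 of 19974 protein-coding genes with a mean of at least 500 bp covered were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend). Calls were made at a Benjamini-Hochberg adjusted p under 0.05. Covered lengths are printed unscaled, and log2 changes are on the scaled scale with the pseudocount, with their standard errors. Overlapping genes share peaks. A covered length can saturate: a gene that lay under peaks over the same length in all 6 libraries still took a log2 change of 0.19 from the scaling alone, because shTDP43 replicate 1 had the shortest total.

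Fixed gene lists were tested with camera at a preset inter-gene correlation of 0.01 and with fry, adjusted over the 15 lists, and each list's calls were also adjusted over the list alone. All list symbols matched the annotation. The lists covered DRIP assay control loci, genes with known TDP-43 cryptic exons, genes mutated in amyotrophic lateral sclerosis (ALS), R-loop resolution factors, cytosine methylation and hydroxymethylation, transposable element silencing, nucleic acid sensing and interferon response, DNA damage response, adrenergic and mesenchymal neuroblastoma identity, synapse, ribosomal proteins, replication-dependent histones, chromosome 19 zinc finger genes and genes over 200 kb.

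Merged regions were made from peaks that touched or overlapped, and a library counted as present from 1 bp of overlap. Numbers of peaks, covered lengths and shares were compared with 2-sided exact permutation tests, which cannot go below p = 0.1 with 3 libraries against 3. Wilson intervals at the 95% level were given for shares of regions, and they cover counting error only. Interval sums were checked against a brute-force count in 500 windows, of which 0 differed. The gene test was tested on simulated values for the 12810 genes, of which 200 were changed. It recovered 57.0% of log2 changes of 1 and 91.0% of log2 changes of 2 in the shTDP43 against shNC design, with 10 false calls among 158. The simulated noise was independent between genes and libraries, without depth differences, saturation or genes without peaks. These shares therefore do not give the false calls among the real ones.

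Groups, tests, lists, most alternatives and the naming rule were fixed before the data were examined. The rule took TARDBP, the 10 largest increases and decreases among called genes, from each list the 2 members with the smallest p and the 2 with the longest mean covered length, and the 5 longest regions present in all libraries of one genotype and none of the other. Genes outside it are said to be so where they appear. The result for 1 gene under this rule is not reported. Alternatives covered stricter peak thresholds, equal peak numbers, removal of peaks also called after RNase H, scaling, pseudocounts, gene filters, the flank, the variance trend, the list test's correlation, merging and overlap rules, a replicate block and each replicate left out. Library weights, centring on 51 neighbouring genes and fits with 2 libraries a genotype were added after the data were seen. Calculations outside R used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.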

Results

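DRIP-seq peak lists were compared between SH-SY5Y neuroblastoma cells with a TDP-43 knockdown hairpin (shTDP43) and with a control hairpin (shNC), with 3 untreated libraries and 1 RNase H-treated library per genotype. The study's title names the R-loop landscape after stable TDP-43 deficiency, and the comparisons follow from that question. The shNC lists held 73456, 69542 and 70902 peaks in replicates 1 to 3, and the shTDP43 lists 57277, 69744 and 70120. The background pileup, a measure of depth, was 2.01, 1.93 and 1.62 in the shNC libraries and 1.05, 1.68 and 1.94 in the shTDP43 libraries. Replicate 1 of shTDP43 was thus the shallowest untreated library, and its peaks covered 91.6 Mb against 125 to 142 Mb in the other 5. No pair of libraries was a duplicate: the Jaccard index of covered bases was at most 0.722, between shTDP43 replicates 2 and 3.

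TARDBP, the gene targeted by the hairpin, lay on chromosome 1 from 11012654 to 11030528 and carried peaks in every untreated library. Its covered length was 14.2, 10.3 and 12.7 kb in the shNC replicates and 6.82, 9.87 and 10.2 kb in the shTDP43 replicates. The log2 change of −0.28 ± 0.12 (SE) did not pass the test (limma, adjusted p = 0.443). Hybrid coverage of the gene does not measure its transcript or protein, so it is no check of the knockdown.

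**Figure D1:**
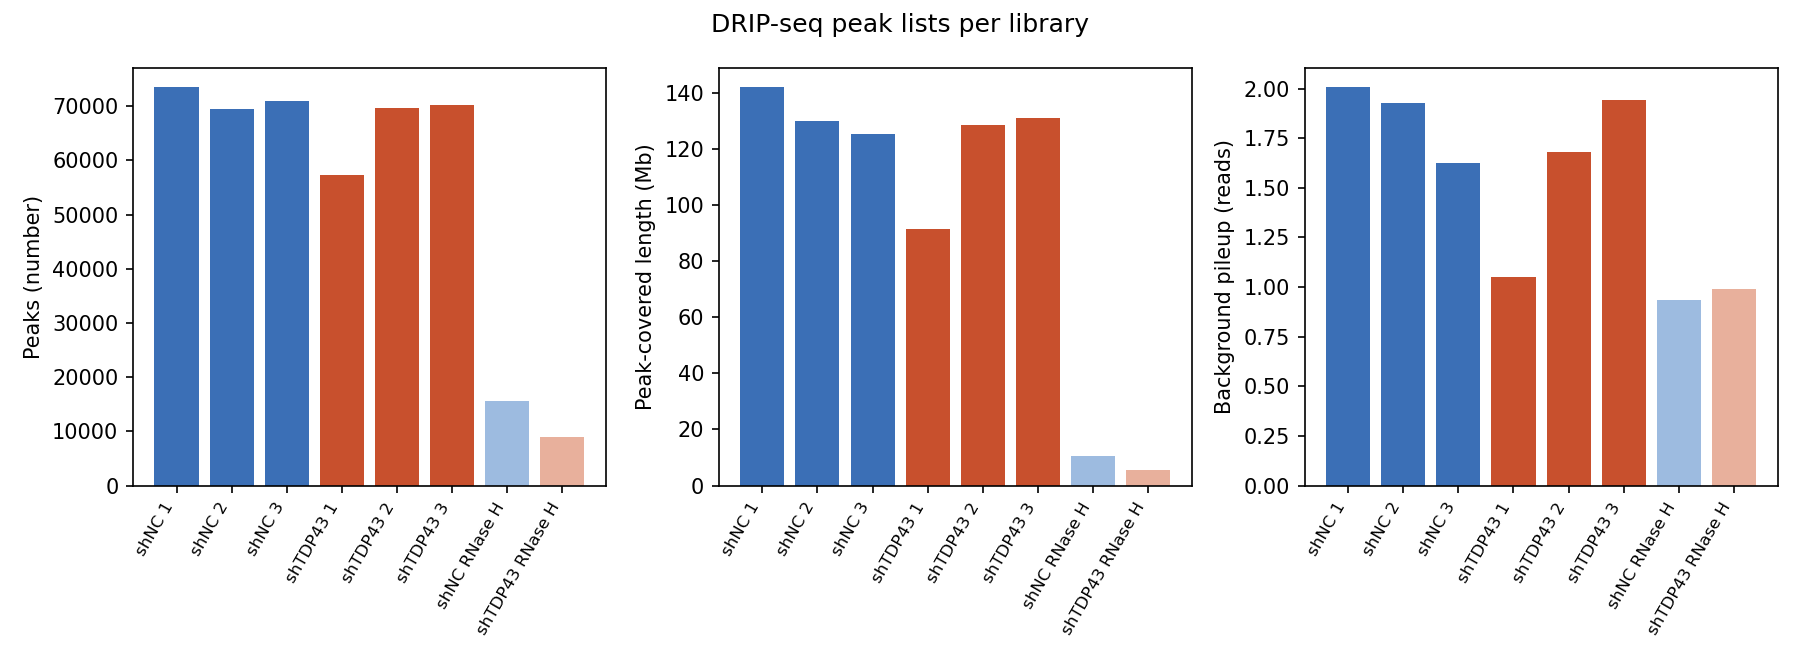
Number of peaks, peak-covered length in Mb and background pileup in reads for each library, 1 bar per library, coloured by genotype with RNase H-treated libraries in pale colours. The treated libraries had 15580 and 8916 peaks, and shTDP43 replicate 1 had the lowest covered length of the untreated libraries, 91.6 Mb.

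RNase H removed most of the called signal in both genotypes. After treatment 15580 peaks covering 10.5 Mb were called in shNC, against 71300 ± 1987 peaks and 132.4 ± 8.55 Mb (SD, n = 3) without it. In shTDP43, 8916 peaks covering 5.66 Mb were called, against 65714 ± 7309 peaks and 117.0 ± 22.02 Mb (SD, n = 3). Only 52.6% of the treated peaks in shNC and 49.1% in shTDP43 overlapped an untreated peak of the same genotype. The treated lists are therefore not simply what was left of the untreated ones. Coverage of PLXNA4, a semaphorin receptor of axon guidance, went from a mean of 112.7 kb in shNC to 10.7 kb after RNase H. Coverage of ALK, a receptor tyrosine kinase and neuroblastoma oncogene, went from 300.04 kb to 13.1 kb. SYT7 and CALM3 had no peak in either treated library. TFPT, a locus often used as a positive control for DRIP, kept 8.77 kb of 10.6 kb in the treated shNC library and 5.22 kb in the treated shTDP43 library. The adrenergic transcription factor gene GATA3 kept 11.2 kb in shNC and 2.55 kb in shTDP43, from means of 30.1 and 29.9 kb. The treated libraries were also shallower, with background pileups of 0.936 and 0.991. At a similar pileup of 1.05, untreated shTDP43 replicate 1 had 57277 peaks.

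Of regions with a peak in at least 2 of 3 untreated libraries, 8.17% (4175 of 51083, 95% Wilson interval 7.94 to 8.41) in shNC and 5.202% (2406 of 46252, 5.00 to 5.41) in shTDP43 overlapped a peak of the treated library of the same genotype. With 1 treated library per genotype, the difference was not tested. Regions that overlapped were longer, with median widths of 4502 bp against 1494 bp in shNC and 3508 bp against 1577 bp in shTDP43. When each treated list was set against the strongest 57204 peaks of every untreated library, the shNC list hit 7.30% ± 0.83 of shNC peaks and 7.17% ± 0.42 of shTDP43 peaks (SD, n = 3). The shTDP43 list hit 4.41% ± 0.75 of shNC peaks and 4.28% ± 0.36 of shTDP43 peaks (SD, n = 3). Cut to its strongest 8868 peaks, the length of the shTDP43 list, the shNC list hit 4.84% ± 0.80 and 4.71% ± 0.35 (SD, n = 3), so the gap mostly followed the length of the treated list. Of the treated covered length, 36.7% in shNC and 41.2% in shTDP43 lay outside coding genes, compared with 13.5% ± 0.42 and 13.1% ± 0.23 (SD, n = 3) in untreated libraries.

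The overall extent of untreated coverage did not pass a test between genotypes. Gene bodies of protein-coding genes held 69.1% ± 0.72 of covered length in shNC and 68.7% ± 1.08 in shTDP43 (SD, n = 3). Windows within 1 kb of either gene end held 17.4% ± 0.55 and 18.1% ± 1.28 (SD, n = 3), a difference of 0.69 percentage points (exact permutation p = 0.6, and 0.6 after adjustment over 3 shares). That difference was −0.0450 percentage points without shTDP43 replicate 1. The number of peaks on the chromosomes used differed by −5588 per library (exact permutation p = 0.3) and the covered length by −15.5 Mb (exact permutation p = 0.5). Without shTDP43 replicate 1 these differences were −1379 peaks and −2.76 Mb. Regions present in all 6 libraries numbered 24021 of 99429 and spanned 71.0% of all region length.

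PLXNA4 had the smallest p-value among genes with less hybrid coverage in shTDP43. Its span on chromosome 7, from 132123340 to 132648688, was covered over 112.7 ± 13.0 kb in shNC and 17.6 ± 5.53 kb in shTDP43 (SD, n = 3). The log2 change was −2.52 ± 0.11 (SE, adjusted p = 1.48e-04). TNS3, a focal adhesion protein, fell from 14.8 ± 2.21 to 2.87 ± 0.29 kb (SD, n = 3), with a log2 change of −2.13 ± 0.15 (SE, adjusted p = 0.00185). NOS1, the neuronal nitric oxide synthase on chromosome 12 from 117208142 to 117361626, had 11.97 ± 1.41 kb in shNC (SD, n = 3). It had 1.07 kb in shTDP43 replicate 2 and no peak in the other 2 untreated shTDP43 libraries (adjusted p = 0.0288). Of the 10 largest decreases, 8 genes had no peak in any untreated shTDP43 library, so no fold is given for them. They were ALS2CL (3.94 ± 1.45 kb in shNC), EVC2 (3.72 ± 0.83 kb), FBP1 (3.49 ± 1.03 kb), CD9 (3.02 ± 0.79 kb), DIO3 (2.71 ± 0.33 kb), PTGER2 (2.69 ± 0.58 kb), GDF10 (2.50 ± 0.70 kb) and HEG1 (2.396 ± 0.06 kb; SD, n = 3 for each). Their adjusted p-values ran from 0.0130 to 0.0455. These values and the rank of the 8 genes depend on the 100 bp added before taking log2. ALS2CL was covered over 3.053 kb in the treated shNC library and 0.538 kb in the treated shTDP43 library, so peaks were called there after RNase H too. Whether they match the untreated peaks was not tested, and covered length does not measure the amount of signal. The tyrosine phosphatase gene PTPRR fell from 3.99 ± 1.62 kb to 0.322 kb in 1 untreated shTDP43 library and no peak in the other 2 (adjusted p = 0.0357). The calls of all 10 largest decreases ended when any 1 shNC library was left out (adjusted p from 0.137 to 0.466), while those of PLXNA4 and TNS3 stayed. The PLXNA4 call ended without scaling (log2 change −2.72, adjusted p = 0.103) and the TNS3 call at a −log10 q of at least 5 (adjusted p = 0.0506).

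Among genes with more coverage, ELAPOR1, a transmembrane protein of the endosome and lysosome, led. Its span on chromosome 1, from 109114115 to 109206781, was covered over 2.16 ± 0.32 kb in shNC and 11.7 ± 3.13 kb in shTDP43 (SD, n = 3). The log2 change was 2.55 ± 0.14 (SE, adjusted p = 6.00e-04). ZBTB40 rose from 0.511 ± 0.174 to 2.48 ± 0.74 kb, and ERVH48-1, a gene derived from an endogenous retrovirus, from 1.32 ± 0.07 to 4.63 ± 0.92 kb (SD, n = 3). GFRA3, a receptor of the GDNF family, rose from 4.22 ± 2.03 to 12.1 ± 2.14 kb, and the lipid phosphatase gene PLPP3 from 5.67 ± 0.81 to 17.7 ± 5.24 kb (SD, n = 3). LUC7L, a splicing factor, had a log2 change of 1.55 ± 0.17 (SE), and PRICKLE1, a planar cell polarity gene, one of 1.42 ± 0.15. The potassium channel genes KCNH1 and KCNMA1 rose by log2 changes of 0.98 ± 0.10 and 0.92 ± 0.12 (SE). Adjusted p-values of these 9 genes ran from 6.00e-04 to 0.0451, and without scaling none of the 9 was called (0.0833 to 0.536). Stricter peak thresholds ended most calls among the 26 genes of the naming rule called in either direction. At a −log10 q of at least 5, 2 stayed called and 21 lost the call, and at 10, 1 stayed and 17 lost it. The rest were not tested at these thresholds. The calls of ZBTB40 and KCNMA1 ended without any 1 of the shNC replicates, that of GFRA3 without shNC replicate 1 or 2, and that of LUC7L without shNC replicate 1. ZBTB40 and GFRA3 also lost the call without any 1 of the shTDP43 replicates.

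In total 22 genes had more and 96 had less coverage in shTDP43, of 12810 tested (limma, adjusted p under 0.05). Called genes were long in both directions, with median spans of 150.3 kb for less and 97.5 kb for more coverage, against 29.2 kb over tested genes. Standard errors could be far smaller in widely covered genes, such as 0.07 for ALK against 0.76 for DIO3. How far this shaped the lengths of called genes was not tested. Without scaling, the median log2 change of all genes moved from 0.05 to −0.15, and 1 gene was higher and 19 were lower. Leaving out shNC replicate 1, 2 or 3 gave 6, 8 or 7 genes with more and 12, 24 or 20 with less coverage, and leaving out shTDP43 replicate 1, 2 or 3 gave 57, 14 or 14 with more and 166, 133 or 108 with less.

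**Figure D2:**
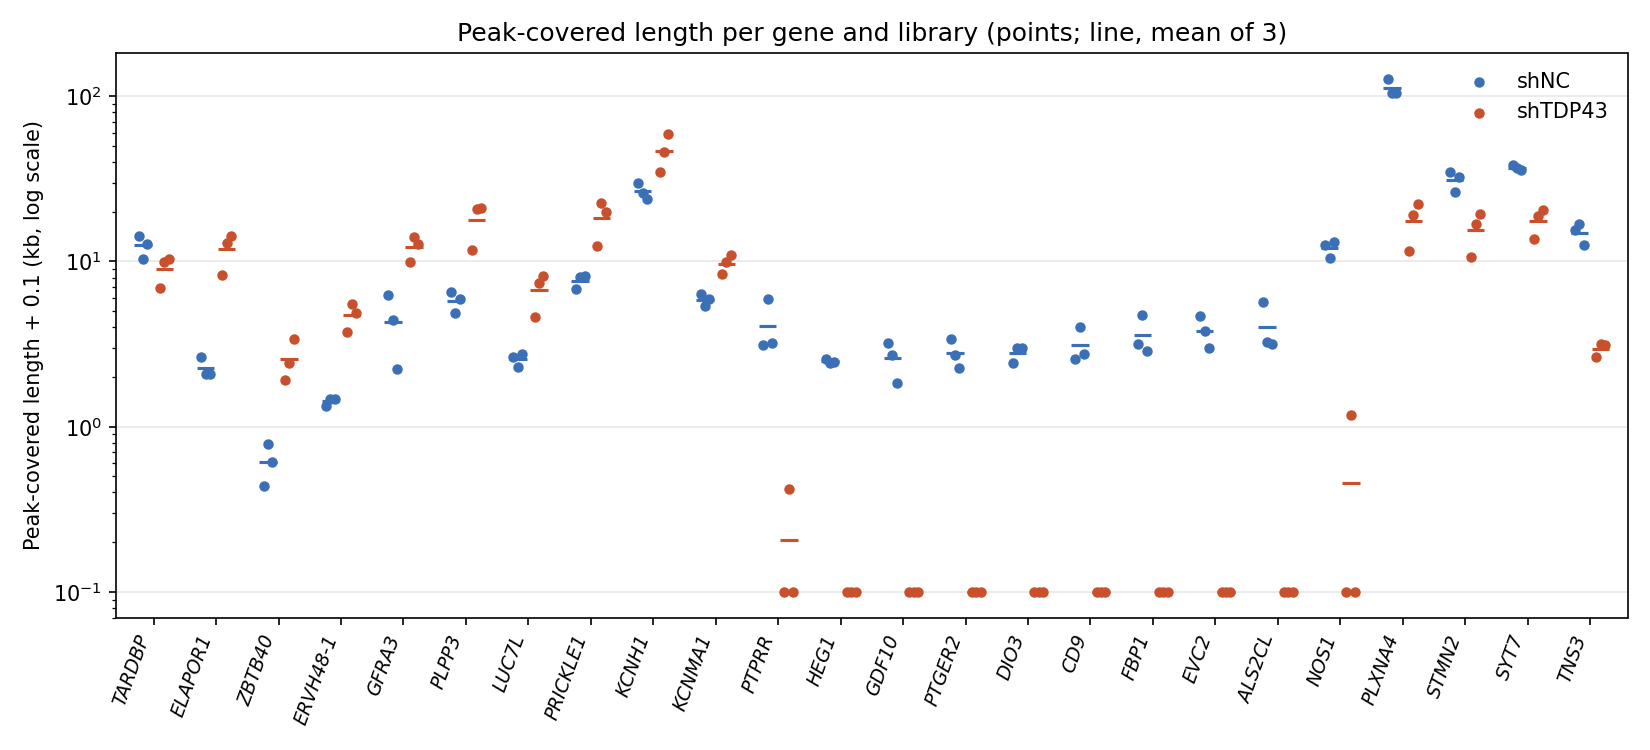
Peak-covered length per gene in kb plus 0.1 on a log scale, with 1 point per untreated library and a line at the mean of 3, shNC in blue and shTDP43 in orange. Points at 0.1 are genes with no peak: 8 of the 10 largest decreases had none in any untreated shTDP43 library, while ELAPOR1 went from a mean of 2.16 to 11.7 kb.

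Genes with known TDP-43 cryptic exons went both ways. Of 27 tested, SYT7 and STMN2 passed, both with less coverage, and 25 did not. SYT7, a calcium sensor of vesicle fusion on chromosome 11 from 61513714 to 61588387, fell from 36.9 ± 1.11 to 17.6 ± 3.60 kb (SD, n = 3; log2 change −0.89 ± 0.07 SE, adjusted p = 0.00252), and its call ended without scaling (−1.09, adjusted p = 0.236) and at a −log10 q of at least 5 (−1.55, 0.0574) or 10 (0.720). STMN2, an axonal microtubule regulator on chromosome 8 from 79611117 to 79666158, fell from 31.0 ± 4.43 to 15.5 ± 4.49 kb (SD, n = 3; log2 change −0.84 ± 0.13 SE, adjusted p = 0.0261). The STMN2 call ended without shNC replicate 1 or 3 (adjusted p = 0.165 for each), without scaling (0.490), without the variance trend (0.139), after centring (0.0648) and at a −log10 q of at least 5 (0.151) or 10 (0.370). Adjusted over the list alone, KALRN (−0.80 ± 0.15 SE) and CAMK2B (−0.42 ± 0.10) were also lower and ATG4B (0.53 ± 0.13) and CELF5 (0.32 ± 0.08) higher. KALRN, CAMK2B, ATG4B and CELF5 lie outside the naming rule and were named after their values were seen. The list as a whole had a median log2 change of 0.00, against a negative mean of −0.08, and was not called by camera (adjusted p = 0.484). The fry test for change in either direction gave an adjusted p of 0.00233, and smaller ones for chromosome 19 zinc finger genes (4.06e-04) and long genes (2.63e-04). Of 23 tested ALS genes none passed, with adjusted p-values of 0.144 for NEK1 (−1.17 ± 0.30 SE) and 0.185 for ANXA11 (−0.88 ± 0.25). At an adjusted p over the list alone none passed either, and the camera adjusted p was 0.959.

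**Figure D3:**
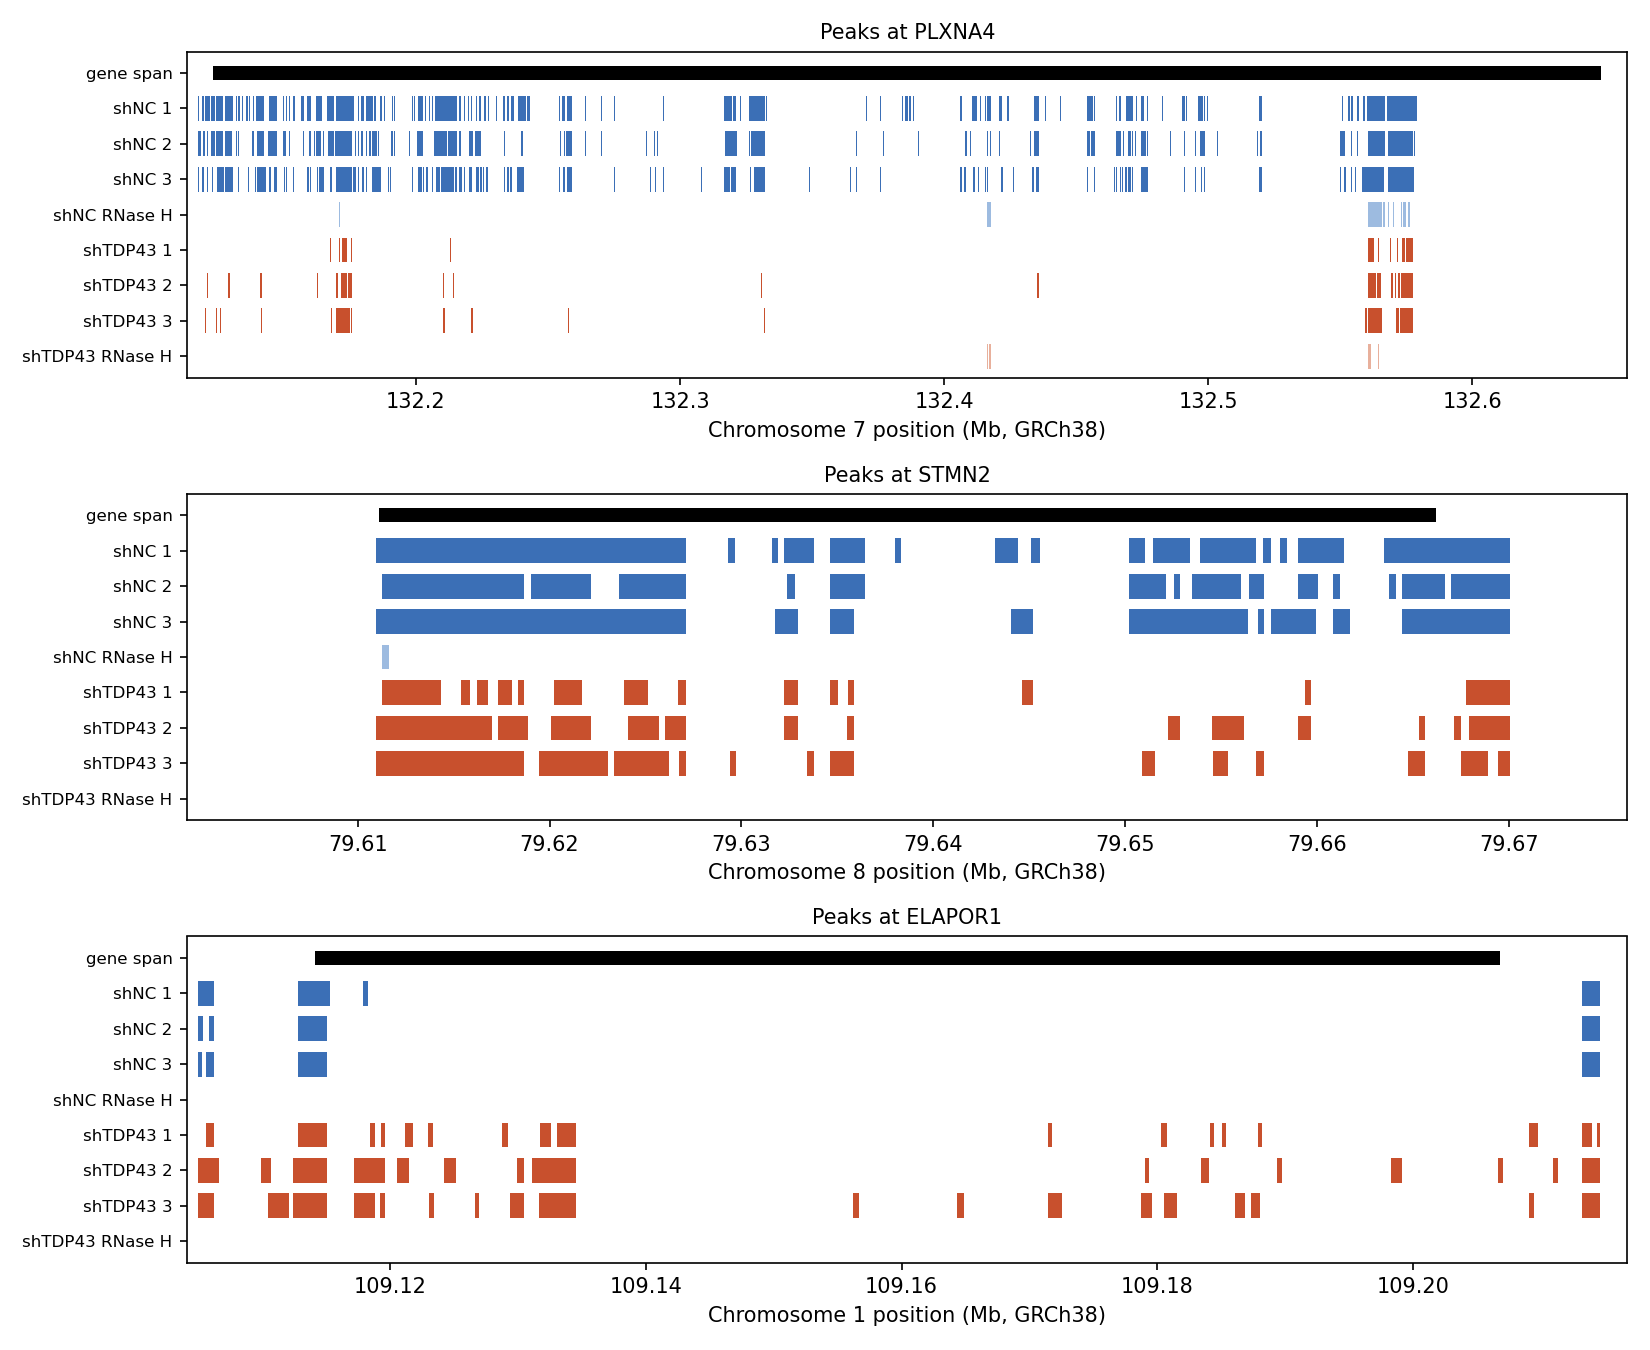
Peaks of each library, as boxes to scale along the chromosome, at PLXNA4, STMN2 and ELAPOR1, with the annotated gene span in black and RNase H-treated libraries in pale colours. Peaks were lost over most of PLXNA4 in the shTDP43 libraries, the first 5 kb of STMN2 stayed covered over a mean of 4.50 kb, and ELAPOR1 gained peaks within its span.

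TET3, which oxidises methylated cytosine, was the called member of the methylation and hydroxymethylation list. Its covered length was 40.4 ± 2.76 kb in shNC and 45.9 ± 9.90 kb in shTDP43 (SD, n = 3; log2 change 0.36 ± 0.06 SE, adjusted p = 0.0408), although replicate 1 of shTDP43, at 34.5 kb, lay below every shNC library before scaling. The call ended without scaling (log2 change 0.16, adjusted p = 0.801) and without shNC replicate 1, 2 or 3 (adjusted p = 0.232, 0.217 and 0.201). It also ended without shTDP43 replicate 2 or 3, at both stricter peak thresholds, without peaks also called after RNase H, with cyclic loess, without the variance trend and after centring (0.0628 to 0.720). The other 12 tested members did not pass. DNMT3A, a DNA methyltransferase, had a log2 change of 0.08 ± 0.10 (SE). The list was called upwards by camera (median log2 change 0.14, adjusted p = 0.0298) and by fry (adjusted p = 0.0122), and its camera adjusted p was 0.509 with an estimated correlation. The camera call also ended without shNC replicate 2 (adjusted p = 0.0650), without shTDP43 replicate 2 (0.0540), with equal peak numbers (0.0541), at a −log10 q of at least 5 (0.248) or 10 (0.930), with either other gene filter (0.0770 and 0.107), without the variance trend (0.0659) and without scaling (0.112), where the median was −0.05.

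Long genes made up 39 of the 96 genes with less coverage and 4 of the 22 with more. Of 916 tested genes over 200 kb, 296 had a positive log2 change, and the median was −0.17. ALK fell from 300.04 ± 26.0 to 199.9 ± 42.4 kb (SD, n = 3; log2 change −0.41 ± 0.07 SE, adjusted p = 0.0393), and its call ended without shTDP43 replicate 1 (adjusted p = 0.0629) and without shNC replicate 1, 2 or 3 (0.229, 0.0940 and 0.212). ZMIZ1, also widely covered, had 244.7 ± 2.17 and 234.5 ± 14.1 kb (SD, n = 3, adjusted p = 0.634). The list was called downwards by camera (adjusted p = 1.32e-09), with an adjusted p of 0.509 with an estimated correlation. Adjusted over the list alone, 109 were lower and 13 higher. Without shTDP43 replicate 1 the median was −0.08.

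Ribosomal protein genes were called upwards by camera (79 tested, median log2 change 0.18, adjusted p = 7.43e-04), but not with an estimated correlation (adjusted p = 0.704) without shTDP43 replicate 1 (0.706) or without scaling (0.0645, median −0.01), and none of the 79 passed singly. RPS3 had a log2 change of 0.19 ± 0.13 and RPS19 of 0.16 ± 0.14 (SE). TFPT, covered over 10.6 kb in all 6 untreated libraries, took a log2 change of 0.19 from the scaling alone.

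No member of the other lists passed singly over all genes. The DRIP control loci (8 tested, median 0.19), adrenergic (20, 0.19), histone (55, 0.19), transposable element silencing (21, 0.14), synapse (19, 0.08), R-loop resolution (28, 0.08) and DNA damage (22, 0.02) lists had positive median log2 changes. Without scaling none of these 7 medians was above 0, from −0.18 for DNA damage to 0.00 for the DRIP controls and histones. The sensing and interferon (9, −0.14), chromosome 19 zinc finger (213, −0.06) and mesenchymal (7, −0.20) lists had negative ones. Camera adjusted p-values were 0.292 for the DRIP controls, 0.0674 for adrenergic, 0.0942 for histone, 0.114 for transposable element silencing, 0.623 for synapse and 0.348 for R-loop resolution genes. They were 0.959 for DNA damage and 0.348 for each of the 3 lists with negative medians. Adjusted over the list alone, DDC, the dopa decarboxylase gene (0.38 ± 0.09 SE), FANCA (0.61 ± 0.13), EIF2AK2, a double-strand RNA sensor (−0.48 ± 0.12), and BTBD19 (−0.50 ± 0.13) passed. Other members with the smallest p in their lists were EHMT1, a histone methyltransferase (0.24 ± 0.07 SE), ATR, a DNA damage kinase (−0.53 ± 0.15), SHANK2, a synaptic scaffold (−0.53 ± 0.13), and ZNF69 (−0.63 ± 0.14). Of the mesenchymal markers, FN1 and NOTCH2 had at most 1.27 kb and 1.54 kb covered in any library, and FOSL2 and NOTCH3 had means of 17.1 and 15.0 kb in shNC.

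**Figure D4:**
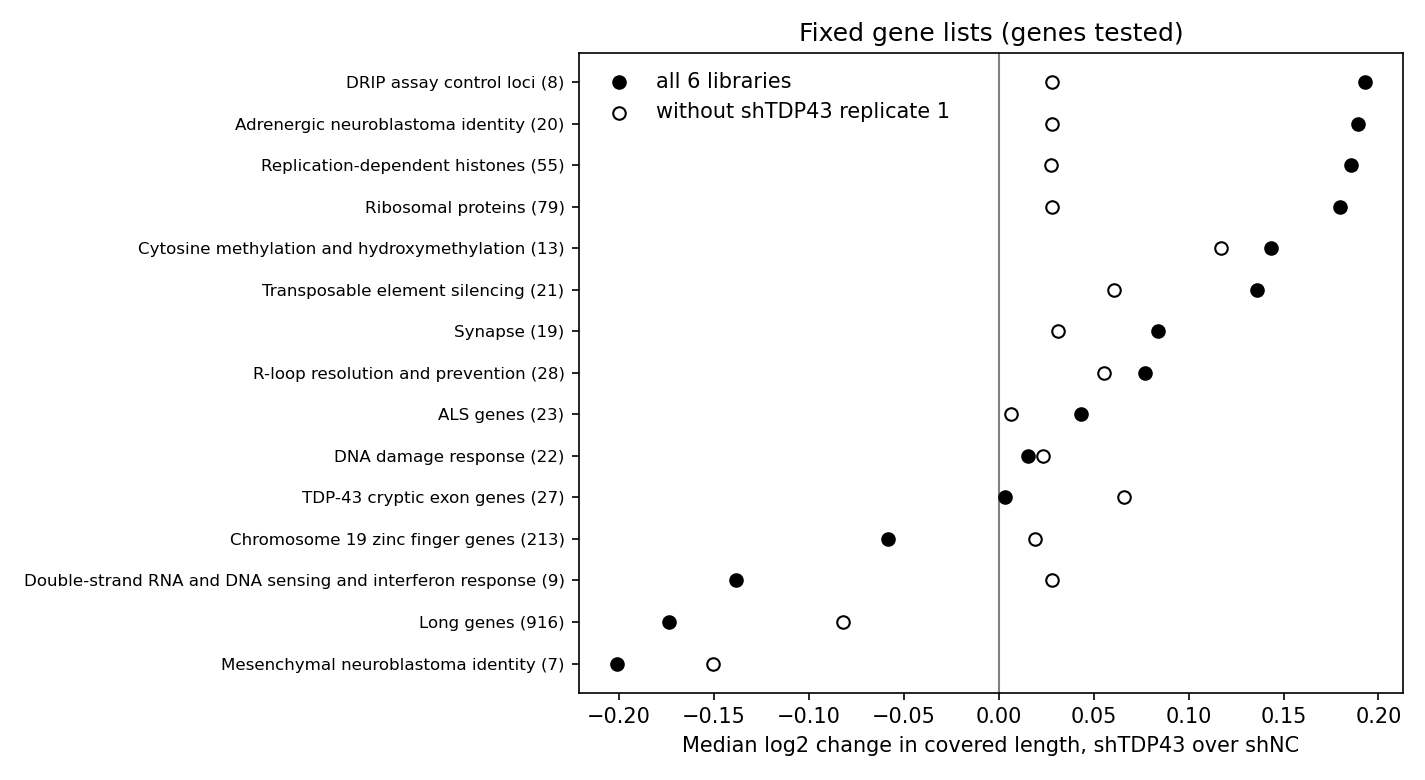
Median log2 change in covered length (shTDP43 over shNC) of each fixed gene list, with the number of tested genes in brackets, for all 6 untreated libraries (filled) and without shTDP43 replicate 1 (open). The median of ribosomal protein genes went from 0.18 to 0.03 without that library, and that of long genes from −0.17 to −0.08.

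Regions present in all 3 untreated libraries of one genotype and in none of the other included loci of called genes. The longest in shNC alone lay on chromosome 14 from 101554982 to 101563393 and held DIO3, the gene of a thyroid hormone-inactivating deiodinase, with DIO3OS and MIR1247. A pair of regions within PLXNA4, at 132180902 to 132187024 and 132316576 to 132321668 on chromosome 7, and one at a gene end of BNC2, on chromosome 9 from 16869160 to 16874532, were among the 5 longest. The remaining one was intergenic, on chromosome 5 from 174328283 to 174334693. In shTDP43 alone, the longest regions lay within PLEKHG4B (chromosome 5, 183956 to 188546), PLPP3 (chromosome 1, 56533985 to 56538069), ELAPOR1 (chromosome 1, 109131110 to 109134513) and ZMAT4 (chromosome 8, 40885553 to 40888950). The other was 8557 bp from GZMM on chromosome 19, from 558480 to 562203. None of these 10 regions overlapped a peak of a treated library.

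In total 1263 regions were found in shNC alone and 257 in shTDP43 alone, with median widths of 950 and 822 bp. PLXNA4 held 27 of the regions in shNC alone, over 54592 bp. Of regions in shNC alone 77.1%, and in shTDP43 alone 81.3%, overlapped a coding gene, compared with 83.6% of all regions. Without shTDP43 replicate 1, 1465 regions were in shNC alone and 1708 in shTDP43 alone. Leaving out each other library gave 2273 to 3459 regions in shNC alone and 407 to 684 in shTDP43 alone. With a library left out, a region had to be present in, or absent from, fewer libraries. These counts therefore follow a looser rule than the 1263 and 257.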

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

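Depth limits these comparisons, since a shallower library loses weak peaks and no read counts were used. The fits with library weights, with centring on 51 neighbouring genes and with 2 libraries a genotype were chosen after seeing the data, and the cause of the changes below was not tested. The restriction-fragment version of the regions was not run, because it needs the genome sequence. The differences in peak number and covered length stayed negative at stricter peak thresholds and without peaks also called after RNase H. With 1 library left out they stayed negative too, and shrank to −1379 peaks and −2.76 Mb without shTDP43 replicate 1. With shNC replicate 1 omitted as well, covered length averaged 127.6 Mb in shNC and 129.6 Mb in shTDP43, so its difference was positive. It was negative when shNC replicate 2 or 3 was omitted instead (133.7 and 135.9 Mb in shNC against 129.6 Mb). The exact permutation tests of peak number and covered length cannot pass 0.05 with 3 libraries a genotype. The difference in gene-end share, planned as a promoter share, ranged from −0.0450 to 1.13 percentage points with 1 library left out, and the negative value came without shTDP43 replicate 1.

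Genes with more and less coverage numbered 3 and 30 at a −log10 q of at least 5, 2 and 30 at 10, and 1 and 19 without scaling. They numbered 40 and 191 with a pseudocount of 1000 bp and 19 and 71 with one of 20 bp. Without the variance trend they were 14 and 61, and with library weights 283 and 475. Genes with more coverage were 44 with equal peak numbers and 14 after centring, and genes with less coverage were 52 without peaks also called after RNase H. Leaving out 1 library gave 6 to 57 with more and 12 to 166 with less. With 2 libraries a genotype, omitting shTDP43 replicate 1 and shNC replicate 1, 2 or 3, limma called 0, 43 or 21 with more and 0, 111 or 71 with less. The first of these fits had 838 genes higher and 839 lower at an unadjusted p under 0.05. Lists past the threshold numbered 3, against 0 with an estimated correlation, 2 to 5 with 1 library left out, and 1 with 2 libraries a genotype when shNC replicate 2 or 3 was omitted. When shNC replicate 1 was omitted, the median of ribosomal protein genes was −0.0222.

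The replicate block gave 9 genes with more and 65 with less coverage. Deviations of same-numbered libraries correlated at −0.17, 0.06 and −0.17 over genes, which gave no sign of pairing. With 3 libraries a genotype, these values cannot exclude that same-numbered libraries were prepared together.

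The shares of regions also called after RNase H were 6.00% in shNC and 3.27% in shTDP43 at a −log10 q of at least 5, 3.26% and 2.29% at 10, 2.63% and 2.03% with 50% of the region covered, and 10.1% and 6.72% for regions in all 3 libraries. They ranged from 8.38% to 9.15% in shNC and from 5.33% to 6.09% in shTDP43 with 1 library left out. Regions in shTDP43 alone and shNC alone numbered 41 and 832 at a −log10 q of at least 5, 24 and 379 at 10, and 117 in shTDP43 alone with peaks within 1 kb merged. With 1 library left out, which loosens the rule for a region, they ranged from 407 to 1708 and from 1465 to 3459. With 2 libraries a genotype they were 3227 and 2927, 2521 and 3578, and 2481 and 3889, omitting shTDP43 replicate 1 and shNC replicate 1, 2 or 3. Omitting shTDP43 replicate 2 they were 1341 and 4283, 1078 and 5145, and 982 and 5488, and omitting shTDP43 replicate 3 they were 1350 and 4688, 1017 and 5508, and 994 and 5996, in the same order.

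For the 26 named genes past the threshold, 379 of 604 values under alternatives stayed past it, 225 lost it and none changed sign. With a pseudocount of 20 bp 13 of these 26 lost the call, and with one of 1000 bp 0 did. For the 52 others, 14 of 1222 values passed. For lists, 343 of 372 values kept their side, 18 lost the call, 10 gained it and 1 changed sign.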

Other observations

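The tests of chance and of the shallow library below, and the choice of the long non-coding genes and chromosomes, came after the results were seen. The tests at STMN2 were set before their results were seen.

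Long non-coding RNA genes, which the comparisons above leave out, moved at some of the same loci. Of 4201 tested in the same way with limma, 2 had more and 6 had less coverage in shTDP43. The annotated spans of 4 of these overlapped no coding gene. Without shTDP43 replicate 1 there were 19 calls. DIO3OS, antisense to the imprinted DIO3 gene, was covered over 5115, 6266 and 5138 bp in the shNC replicates and had no peak in any untreated shTDP43 library (adjusted p = 0.00691). It is among those 4, but the region in shNC alone from 101554982 to 101563393 held both DIO3OS and DIO3. Its call is therefore not separate from that of DIO3. C15orf32 on chromosome 15, from 92471677 to 92501117, had no peak in any untreated shNC library and 1995, 2324 and 3248 bp in the shTDP43 replicates (adjusted p = 0.0455), and this call ended without shTDP43 replicate 1 (adjusted p = 0.112). Its neighbourhood holds ST8SIA2, a polysialyltransferase gene outside the naming rule and named after its value was seen, that rose by a log2 change of 0.91 (adjusted p = 0.0102). The oncogene-linked PVT1 had a log2 change of −0.86 ± 0.15 (SE), short of the threshold (adjusted p = 0.0735).

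Shares of covered length by chromosome were apart between genotypes, with all 3 shTDP43 libraries on one side of all 3 shNC libraries, for 8 of 23 chromosomes, where chance gives 10% for each. Shares of one library add up to a whole, so the chromosomes are not independent. Of the 8, 3 were higher and 5 lower in shTDP43. Chromosome 16 took 5.80% ± 0.15 of covered length in shTDP43 and 5.48% ± 0.0035 in shNC, and chromosome 20 took 3.25% ± 0.04 and 3.10% ± 0.01, while chromosome 3 took 4.64% ± 0.14 and 4.82% ± 0.06 (SD, n = 3).

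The 118 called genes were weighed first. The real grouping gave 118 calls and the highest of the other 9 splits gave 0, but 10 splits are too few for a share under 0.05. Lower depth of shTDP43 replicate 1 as the whole cause was argued against, since 110 of the 118 were still called without it, although 0 genes were called when shNC replicate 1 was omitted as well. A copy number or chromatin difference spanning most of 51 neighbouring tested genes was also argued against. The median called gene kept 97.4% of its log2 change after centring on them, although only 74 stayed called. A shorter run of genes would barely move their running median. A copy number or chromatin difference over a single gene or a shorter run was therefore not tested and stays open. So do a difference between the stable lines that has nothing to do with TDP-43 and the knockdown itself, which were not tested.

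The excess of losses was weighed next, at 1263 regions lost against 257 gained, a ratio of 4.91. The real grouping gave 1520 such regions and the highest other split 1082, again with too few splits. With 2 libraries a genotype and without shTDP43 replicate 1, the ratio was 0.907, 1.42 and 1.57, omitting shNC replicate 1, 2 or 3, at background pileups of 1.77, 1.81 and 1.97 in shNC against 1.81 in shTDP43. The 6 choices of 2 libraries a genotype that keep shTDP43 replicate 1 gave 3.19 to 6.03, so most of the excess came with that library. Without it the ratio was 1.42 at pileups of 1.81 and 1.81, but 0.907 at 1.77 in shNC and 1.81 in shTDP43. At similar pileup it thus fell on both sides of 1, and the lower depth of that library as the whole cause stays open. Of called genes 74.4% were lower without that library, compared with 81.4% with it, and with shNC replicate 2 or 3 omitted as well 43 and 21 had more and 111 and 71 less coverage, but with shNC replicate 1 omitted none was called and 838 were higher and 839 lower at an unadjusted p under 0.05, so the 3 fits leave depth open there too.

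The position of the loss within STMN2 was weighed last. Its first 5 kb kept 4.50 ± 0.87 kb of coverage against 4.94 ± 0.10 kb in shNC, the next 10 kb kept 6.50 ± 2.32 against 9.40 ± 1.04 kb, and the remaining 40.0 kb kept 4.39 ± 1.45 against 15.7 ± 3.12 kb (SD, n = 3). STMN2 transcripts are known to end early, within the first intron, when TDP-43 is lost, and a hypothesis is that hybrids beyond that point are lost with them. The contrast between covered end and rest was larger in STMN2 than in 80.3% of 66 compared genes with less coverage, and 12 genes exceeded it. In 74.2% of them the better covered end kept more than the rest, with medians of 73.4% and 42.6% kept, computed on lengths scaled to the library total. Peaks filled at least 90% of the end window in shNC in 19 of the 66 genes and 98.9% in STMN2. A filled window can stay covered while its signal falls. The end of SAMD4A was filled over 5 kb in every untreated library. Its 116.0% kept therefore came from the scaling alone, while the rest of that gene kept 53.0%. The filled end of KCNT1 did fall, and kept 37.3% against 53.6% in the rest. These shares therefore decide nothing, and a truncation particular to STMN2 and a general keeping of signal at gene ends cannot be told apart.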
